A study of Homo sapiens with 36 samples.

How the data were processed

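Total RNA of MRC-5 cells was extracted with TRIzol, made into stranded total RNA libraries and sequenced from 1 end on an Illumina HiSeq system. The label of the sequenced molecule reads genomic DNA, while the extraction protocol describes RNA. The 36 libraries are 4 conditions at 3 times with 3 libraries each. All cells were transduced at the same time, and times count days after forskolin (10 µM) and dorsomorphin (1 µM) were added to the FD and NFD cells. The labels do not state whether the 3 libraries of a group are separate cultures.

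The authors aligned reads to GRCh37 (hg19), and their processing notes name TopHat 1.4.1, Cufflinks 2.1.0 and Cuffdiff 2.1.0. Their 9 tables compare FD, N and NFD with GFP at 0.5, 1 and 2 DPT, and each holds 23146 loci. Per the file headers, the authors give for each locus the FPKM of the GFP group and of the other group, 1 value per group of 3 libraries. The deposited log2 fold change is the condition over GFP, and its sign was checked against the pair of FPKM values. The deposited p-value and q-value come from the authors' own test, and the deposited column of significance reads yes exactly where the q-value is at or under 0.05. The smallest deposited p-value is 5e-05 in every table. The smallest q-value is 0.000151 in every table although the number of genes at that p-value differs, so the deposited q-values were adjusted over more tests than 1 table holds. Loci the authors marked as not tested, with too little data, with too many fragments or as failed were left out of every count. Some of these are listed at 0 whatever their level: EEF1A1 in GFP cells, NEUROG2 in NFD cells and CDKN1A in N cells at 1 DPT are examples. A fold change is infinite for 949 tested values across the tables, where a group is listed at 0, and for those genes no fold is given here. In 134 cases the fold change differs from the ratio of the FPKM values by more than 0.001. Each table has 26 gene names turned into date numbers by a spreadsheet, and those loci were counted but are not named. Values per library and read counts were not analysed here, so the depth of each library and the precision it gives are unknown. Coordinates are those of the authors' tables.

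A gene was called where the authors' q-value was at or under 0.05, in the direction of the deposited log2 fold change. Values were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Groups, comparisons, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

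Genes named in the text are NEUROG2, members of the fixed lists, and for each condition the 10 largest rises and the 10 largest falls at 2 DPT among genes called in the same direction at all 3 times, with at least 1 FPKM in the higher group and a value above 0 in both. For NFD against N the same rule was applied to differences with the same sign at all 3 times that were tested against GFP in both tables, since the authors' tables hold no test of NFD against N. A gene named outside this rule is said to have been chosen after its values were seen. Some genes that meet this rule are not reported here.

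The 38 lists hold 654 members, 636 of them different, and 624 of these were found in the authors' tables by symbol. They cover proneural genes, neuronal cytoskeleton and RNA binding, synapse and excitability, motor and other neuron subtypes, SOXC factors, Notch, cAMP and CREB targets, adenylyl cyclase and PKA, BMP SMAD targets, fibroblast matrix, myofibroblast and TGF-beta targets, replication, G2/M, CDK inhibitors and p53 targets. They further cover sterol and fatty acid synthesis, serum response, interferon, inflammatory secretion, ATF4 and ER stress, heat shock, oxidative stress, hypoxia, chromatin remodelling, EMT regulators, skeletal muscle, glia, neural progenitors, neural crest, endothelium and blood, histones, ribosomal proteins, housekeeping genes, axon guidance and neuropeptides. None of the 9 symbols of the mitochondrial genome list matched, and that list was not analysed here. For each list and table with at least 3 tested members, the median of the deposited log2 fold change was set against 10000 random lists of the same size matched on 20 bins of expression (seed 1), with a two-sided permutation p and Benjamini-Hochberg adjustment over all lists and tables. The smallest p this can give is 2e-04, and 0.000991 is the smallest adjusted p it gave. Genes of a list are not replicates, so this p says only whether the list stands apart from other genes of like expression. Members near 0 in both groups were mostly not tested, so for lists near 0 in GFP cells a positive median is partly fixed by that selection. Members called were counted by the authors' q-value and again with their p-values adjusted over the list alone. Tested on simulated data at NFD 2 DPT (14013 genes), 2.5% of 200 unshifted lists had a p under 0.05 and 59% of 200 lists shifted by 0.5 did.

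NFD was compared with N by subtracting the deposited log2 fold changes, which share the GFP group, and the combination with the sum of both effects by subtracting N and FD from NFD. The planned test needed test statistics and was replaced by a count of differences of at least 2-fold. An approximate test was added after the data were seen. It infers each standard error from the authors' p-value (none where p is above 0.95), counts the spread of GFP in each table and applies Benjamini-Hochberg. No p-value is under 5e-05, so a standard error cannot be inferred below a fixed share of its fold change. Genes with large folds against GFP in both tables can therefore seldom pass. The same test compared the fold changes at 0.5 and 2 DPT. Tested on simulated data for NFD against N at 2 DPT (13210 genes), it called 27% of 100 genes changed by 1 on the log2 scale, 43% of 100 changed by 2, and 0 of 13010 unchanged genes. A variant left out the GFP spread, which cancels from NFD minus N, assuming equal spread in all groups. It called 50% and 83%, and 13 of 13010 unchanged genes. Against the sum of both effects this variant kept 1 copy of the GFP spread.

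Overlap of calls was set against the count for independent lists and against 100 simulations of unchanged groups that share a control, with an assumed correlation of 0.5. Correlations of fold changes are across genes, which are not independent replicates. The alternatives were a q-value threshold of 0.01, at least a 2-fold change, at least 1 FPKM in either group, pseudocounts of 1 and 0.1 FPKM, centring on the median of tested genes and the variants of the approximate test.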

Results

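Total RNA was sequenced from MRC-5 cells, an established line of human fetal lung fibroblasts, during a conversion of fibroblasts toward neurons driven by NEUROG2, a proneural transcription factor of the basic helix-loop-helix family. The 36 libraries fell into 12 groups of 3 replicates, made of 4 conditions at 3 times. GFP cells carried a GFP lentivirus. FD cells carried the same virus and received 10 µM forskolin, an activator of adenylyl cyclase, and 1 µM dorsomorphin, an inhibitor of BMP type I receptors and of AMPK. N cells carried a NEUROG2 lentivirus, and NFD cells carried NEUROG2 and received both molecules. Times were 0.5, 1 and 2 days post treatment (DPT) with the molecules. The comparisons asked what the molecules did to fibroblasts, what NEUROG2 did, and what the molecules added to NEUROG2.

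The values compared are the authors' group FPKM and their log2 fold changes against GFP of the same time, on GRCh37 (hg19). Each is 1 value per group of 3 libraries, so no error per group is given here, and sequencing depth is unknown. P-values measure only the spread between the libraries of a group, which may be technical replicates. A gene "rose" or "fell" where the authors' q-value was at or under 0.05. Where 3 values follow a gene or a gene group, they are for 0.5, 1 and 2 DPT in that order, and gene values are the authors' deposited log2 fold changes. The count of members adjusted over the list alone was the same as the count over all genes unless it is given beside it. One label puts the GFP cells in a medium with serum and another puts them in neuron induction medium, the medium of FD, N and NFD cells, so each comparison with GFP may include a change of medium.

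NEUROG2 itself (chromosome 4, 113434671 to 113437328) was listed at 2616, 2565 and 2641 FPKM in N cells in the authors' deposited tables, a rise of 6.16, 7.12 and 7.43 on the log2 scale. GFP cells, which received no NEUROG2 virus, were listed at 36.7, 18.5 and 15.3 FPKM. FD cells were listed at 12.7, 12.3 and 15.4 FPKM, with log2 fold changes of -1.53 and -0.58 that passed and 0.01 that did not. The deposited NFD tables list NEUROG2 at 0 with a mark for loci with too many fragments, so no NEUROG2 value is given for NFD cells.

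In FD cells, the transcripts that answer to cyclic AMP rose within 0.5 DPT and stayed up. The orphan nuclear receptors NR4A1 (chromosome 12, 52416615 to 52453291) with 5.60, 5.80 and 4.48, NR4A2 with 4.13, 4.42 and 3.86 and NR4A3 with 5.22, 6.07 and 5.04, early targets of CREB, rose in the authors' deposited tables. SIK1, a kinase that restrains CREB coactivators, rose by 4.35, 4.72 and 4.56, and PDE4D, a cAMP phosphodiesterase, by 3.44, 3.56 and 3.56. RGS2, a regulator of G protein signalling, rose by 3.55, 4.23 and 2.86, and PPARGC1A, a coactivator of mitochondrial genes, by 2.03, 3.46 and 3.71. FOS, an immediate early gene, rose by 4.84, 3.03 and 1.46. Of the cAMP and CREB targets, 23, 23 and 21 of the 27, 26 and 26 tested members rose and 2, 2 and 2 fell (23, 23 and 21 and 2, 2 and 3 adjusted over the list alone). Medians were 1.79, 1.75 and 1.60 (adjusted permutation p = 0.000991 at each time). FOSL1, an AP-1 member, and TRIB1, a pseudokinase, were the members that fell, with -1.70, -2.06 and -1.88 for FOSL1 and -0.70, -0.44 and -0.78 for TRIB1. Among genes of the adenylyl cyclase and protein kinase A (PKA) pathway, 7, 7 and 8 of 15 tested members rose and 3, 3 and 4 fell (8, 7 and 8 and 3, 3 and 4 adjusted over the list alone). Medians were 0.25, 0.23 and 0.34 (adjusted permutation p = 0.0458, 0.0315 and 0.00504). AKAP12, a scaffold of PKA, rose by 2.27, 2.65 and 2.42.

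Across all genes, 2307 rose and 2441 fell in FD cells at 0.5 DPT, 2100 and 2917 at 1 DPT, and 2251 and 2868 at 2 DPT, of 12961, 13092 and 13302 tested by the authors. At least 2-fold changes numbered 794, 990 and 1103 of these. The same direction was called at all 3 times for 920 rises and 1252 falls. Among the 10 largest lasting rises in the authors' deposited tables were SMOC1, a secreted matricellular protein (5.80, 7.15 and 8.32), DNER, a neuronal ligand of Notch (3.08, 4.00 and 6.12), KDR, a receptor of VEGF (4.32, 5.31 and 5.83), IL1B, an inflammatory cytokine (5.19, 5.55 and 5.52), SSTR2, a somatostatin receptor (1.71, 3.68 and 5.32), and PDE3A, a phosphodiesterase (4.80, 5.22 and 5.22). With a pseudocount of 1 the values at 2 DPT were 4.86 for SMOC1, 3.67 for DNER, 3.42 for PDE3A, 2.65 for SSTR2, 2.47 for KDR and 2.22 for IL1B. The 10 largest lasting falls included SLC14A1, a urea transporter (-3.02, -4.05 and -4.04), OXTR, the oxytocin receptor (-3.17, -4.36 and -3.91), OLR1, a receptor of oxidised lipoprotein (-2.28, -3.60 and -3.75), and ANO1, a chloride channel (-1.11, -3.30 and -3.72), in the deposited tables. With the pseudocount these became -1.37 for SLC14A1, -2.43 for OXTR, -2.42 for OLR1 and -1.30 for ANO1 at 2 DPT.

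Contractile and matrix transcripts fell in FD cells. TAGLN, an actin-binding protein of smooth muscle, fell in the authors' deposited tables (-0.27, -0.83 and -3.01), as did CYR61, a target of YAP and serum (-2.75, -1.83 and -2.51). COL1A1, a fibrillar collagen (-0.83, -0.98 and -1.33), and VIM, the intermediate filament vimentin (-0.47, -0.91 and -1.48), fell as well. Between 0.5 and 2 DPT the approximate test of the fold change passed for TAGLN (-2.75) and did not for COL1A1 (-0.50), VIM (-1.01) or CYR61 (0.24). With standard errors bounded by the smallest p-value, differences of this size could not pass for COL1A1, VIM or CYR61. For these genes the test cannot decide whether the fold changed with time. Of the fibroblast matrix list, 0, 1 and 2 of 24 tested members rose and 11, 14 and 18 fell (0, 1 and 2 and 11, 14 and 19 adjusted over the list alone). Medians were -0.29, -0.37 and -0.49 (adjusted permutation p = 0.000991, 0.00317 and 0.00317). Of the myofibroblast and TGF-beta targets, 5, 5 and 4 of the 19, 19 and 18 tested members rose and 11, 12 and 12 fell. Medians were -0.27, -0.53 and -1.31 (adjusted permutation p = 0.0180, 0.000991 and 0.000991). The TGF-beta ligands TGFB2 (0.87, 1.26 and 1.37) and TGFB1 (0.86, 0.59 and 0.34) were among those that rose.

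Serum-response and immediate early genes fell as a group, while FOS and JUNB rose early. EGR1, a zinc finger factor induced by growth factors, fell (-2.61, -3.74 and -2.43), and DUSP6, an ERK phosphatase, fell (-1.68, -1.79 and -2.12) in the authors' deposited tables. MYC, a growth factor-induced transcription factor (-0.58, -1.23 and -1.47), and SPRY2, a feedback inhibitor of receptor tyrosine kinases (-1.34, -1.35 and -1.53), fell too. In this list 4, 3 and 2 of the 21, 20 and 21 tested members rose and 13, 15 and 16 fell (4, 3 and 2 and 13, 16 and 16 adjusted over the list alone). Medians were -0.47, -0.69 and -0.99 (adjusted permutation p = 0.000991 at each time). JUNB rose at 0.5 and 1 DPT (1.38 and 0.90) and was -0.03 at 2 DPT without passing.

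BMP targets moved apart in FD cells. ID1 (-1.05, -1.54 and -1.24) and ID2 (-1.76, -1.14 and -0.99), inhibitors of basic helix-loop-helix factors, fell in the authors' deposited tables, and so did the inhibitory SMADs SMAD6 (-1.01, -0.77 and -0.71) and SMAD7 (-0.76, -0.95 and -0.84). ID3 rose (1.91, 3.14 and 1.65). Of this list 5, 7 and 5 of the 18, 18 and 19 tested members rose and 8, 7 and 7 fell (5, 7 and 5 and 8, 8 and 7 adjusted over the list alone), and the list medians of -0.10, -0.09 and -0.13 (adjusted permutation p = 0.726, 0.903 and 0.445) did not pass.

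Sterol genes rose early in FD cells and were lower than in GFP cells at 2 DPT. HMGCS1, an enzyme of the mevalonate pathway, went from 1.49 at 0.5 DPT to -0.54 and -0.66 in the authors' deposited tables. In the sterol synthesis list 15, 7 and 0 of the 18, 18 and 17 tested members rose and 0, 5 and 10 fell (16, 7 and 0 and 0, 5 and 10 adjusted over the list alone). Medians were 0.91, 0.04 and -0.37 (adjusted permutation p = 0.000991, 0.800 and 0.00247). In the fatty acid synthesis list 9, 8 and 2 of 10 tested members rose and 0, 0 and 3 fell (10, 8 and 2 and 0, 1 and 3 adjusted over the list alone). Medians were 0.60, 0.34 and -0.09 (adjusted permutation p = 0.000991, 0.0183 and 0.578). FADS1, a fatty acid desaturase, rose throughout (1.17, 1.14 and 0.51). Secreted inflammatory factors rose: IL1A (3.17, 3.32 and 3.05), PTGS2, the inducible cyclooxygenase (3.79, 3.43 and 1.83), and IL11 (2.20, 2.05 and 1.74) in the deposited tables. Of that list 10, 9 and 9 of the 12, 12 and 14 tested members rose and 0, 0 and 2 fell. Medians were 0.96, 1.04 and 1.23 (adjusted permutation p = 0.000991 at each time).

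Several transcripts of neurosecretion were higher in FD cells, which carried no NEUROG2 virus. CHGB, a granin of secretory granules, rose by 4.43, 4.49 and 3.07, SCG2, another granin, by 1.88, 2.84 and 3.52, and SNAP25, a SNARE protein of exocytosis, by 1.57, 1.96 and 3.38 in the authors' deposited tables. Of the synapse and excitability list 7, 7 and 8 of the 12, 11 and 15 tested members rose and 2, 2 and 2 fell (7, 7 and 10 and 2, 2 and 2 adjusted over the list alone). Medians were 0.48, 0.35 and 1.17 (adjusted permutation p = 0.00504, 0.0147 and 0.000991). MBP, a myelin protein with wider splice forms, rose by 1.91, 2.55 and 3.19, and of the glial list 3, 5 and 5 of the 5, 7 and 8 tested members rose and 0, 1 and 1 fell. Medians were 0.29, 0.69 and 1.21 (adjusted permutation p = 0.232, 0.00674 and 0.00179). At 2 DPT 42 transcripts were at least 4 times the level of every other group, 4 of them members of the neuronal lists, such as GRIA2, a glutamate receptor subunit, at 1.18 FPKM, and 14 of them small RNAs. Without genes at least 4 times the level of every other group, chosen after the data were seen, 5112 genes changed at 2 DPT. SOX4 (0.83, 1.10 and 0.55) and SOX11 (0.85, 1.31 and 0.93), factors of neuronal differentiation, rose in the deposited tables, and of the 3 SOXC factors 2, 3 and 2 of 3 tested members rose and 0, 0 and 0 fell. Medians were 0.83, 1.10 and 0.55 (adjusted permutation p = 0.0177, 0.0147 and 0.0685). HES1 (1.64, 1.88 and 1.24) and HES4 (2.51, 3.09 and 1.83), Notch effectors, rose in the deposited tables. In the Notch list as a whole 4, 4 and 4 of the 9, 9 and 10 tested members rose and 4, 4 and 4 fell, and no median passed (-0.09, -0.10 and -0.10 (adjusted permutation p = 0.791, 0.931 and 0.591)).

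In N cells, the cascade downstream of a proneural factor was on at the earliest time. DLL3 (6.78, 8.04 and 6.73) and DLL1 (5.33, 5.47 and 4.18), Notch ligands, rose in the authors' deposited tables, and HES6, a neurogenic antagonist of HES1, by 5.03, 4.56 and 3.81. GADD45G, a stress and neurogenesis gene, rose by 5.75, 6.24 and 5.53, IGFBPL1, a relative of the binding proteins of insulin-like growth factors, by 9.05, 10.42 and 9.68, and EBF3, a factor of neuronal differentiation, by 3.10, 3.18 and 2.60. INSM1, a zinc finger factor of neuroendocrine cells, was listed at 0 in GFP cells and rose at 1 and 2 DPT, and NEUROD1, a downstream proneural factor, rose from 0 at 1 DPT and was 7.17 at 2 DPT without passing. In the proneural cascade list 8, 12 and 10 of the 9, 13 and 15 tested members rose and 0, 0 and 0 fell. Medians were 5.33, 8.04 and 5.68 (adjusted permutation p = 0.000991 at each time). Over all 24 members median levels were 0.0185, 0.00774 and 0.0180 FPKM in GFP cells and 0.246, 0.847 and 1.85 in N cells. These folds thus rest on control values near 0, and members with such values had little room to fall. Such members were mostly tested only where N cells were higher, so positive medians are partly fixed by that selection. Different members were tested at each time, so the medians of the folds do not trace a time course.

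Neuronal structure genes followed in part. SCG2 rose by 5.69, 5.86 and 7.31, CHGB by 3.39, 4.59 and 4.87 and GAP43, a growth cone protein, by 3.15, 3.60 and 3.49 in the authors' deposited tables, and SYP, a synaptic vesicle protein, by 1.85 and 4.22 at 1 and 2 DPT. SYT1, the calcium sensor of vesicle release, rose by 1.77, 1.16 and 1.20. TUBB3, a tubulin used as a neuronal marker that these fibroblasts already expressed at 159 FPKM in GFP cells at 2 DPT, fell (-0.81, -1.54 and -1.79). DCX, a microtubule protein of migrating neurons, was not tested by the authors. Of the synapse and excitability list 5, 10 and 9 of the 13, 14 and 14 tested members rose and 2, 2 and 2 fell. Medians were 0.07, 0.80 and 1.27 (adjusted permutation p = 0.996, 0.0272 and 0.000991). In the list of neuronal cytoskeleton and RNA binding genes 4, 4 and 5 of the 10, 12 and 13 tested members rose and 4, 3 and 2 fell, and no median passed (0.12, 0.29 and 0.29 (adjusted permutation p = 0.983, 0.494 and 0.529)).

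Members of the skeletal muscle list rose beside the neuronal transcripts. CHRNA1, the muscle acetylcholine receptor subunit, rose by 5.50, 6.13 and 5.37 in the authors' deposited tables. TNNT2, the cardiac troponin T, rose by 8.34, 7.92 and 6.27, and MEF2C, a factor of muscle and neurons, by 2.25, 2.29 and 2.00. MYOD1 and MYOG, the myogenic basic helix-loop-helix factors, were not tested. In the skeletal muscle list 10, 5 and 7 of the 11, 12 and 12 tested members rose and 1, 1 and 0 fell. Medians were 5.50, 6.17 and 4.71 (adjusted permutation p = 0.000991 at each time). Levels over all 20 members had medians of 0.0486, 0.0538 and 0.0680 FPKM in GFP cells and 0.758, 0.833 and 0.929 in N cells. The same limits apply here, since control values were near 0 and the tested members changed with time.

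Targets of BMP signalling rose strongly in N cells. ID1 (chromosome 20, 30193085 to 30194317) rose by 5.91, 6.40 and 5.45, ID3 by 4.85, 5.08 and 3.66, ID4 by 3.77, 3.49 and 3.21 and ATOH8, a helix-loop-helix factor, by 4.57, 4.15 and 3.84 in the authors' deposited tables. GREM1, a secreted BMP antagonist, fell (-4.69, -5.14 and -5.05), and BAMBI, a decoy receptor, (-0.56, -1.27 and -1.57). Of this list 15, 15 and 13 of the 20, 20 and 19 tested members rose and 3, 4 and 3 fell (15, 16 and 13 and 3, 4 and 3 adjusted over the list alone). Medians were 1.35, 1.26 and 1.15 (adjusted permutation p = 0.000991 at each time).

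Across all genes, 3537 rose and 3290 fell in N cells at 0.5 DPT, 3481 and 4020 at 1 DPT, and 3737 and 4131 at 2 DPT, of 13520, 13722 and 13774 tested by the authors. At least 2-fold changes numbered 2131, 2506 and 2788, and 2057 rises and 2261 falls held at all 3 times. The 10 largest lasting rises included MGP, an inhibitor of calcification (8.83, 9.97 and 9.51), COL10A1, the collagen of hypertrophic cartilage (all 3 times, 7.13 and 8.57 at 0.5 and 2 DPT), SYT7, a calcium sensor of exocytosis (5.79, 7.06 and 8.24), ITGA9, an integrin (7.56, 8.19 and 8.14), and SSTR2 (6.66, 7.05 and 7.85) in the authors' deposited tables. With a pseudocount of 1 the values at 2 DPT were 7.70 for MGP, 5.41 for COL10A1, 5.01 for SSTR2, 4.30 for ITGA9 and 3.90 for SYT7. Among the 10 largest lasting falls were FGL2, a fibrinogen-like protein (-2.41, -4.45 and -6.53), GDF5, a BMP family ligand (-4.42, -5.11 and -6.17), PTX3, a pentraxin of innate immunity (-5.12, -5.23 and -5.35), IGFBP5, a carrier of insulin-like growth factors (-3.95, -4.69 and -5.10), and ADAMTS1, a protease of the matrix (-3.90, -4.43 and -4.60), in the deposited tables. With the pseudocount these were -4.80 for FGL2, -4.27 for GDF5, -4.72 for PTX3, -4.93 for IGFBP5 and -4.16 for ADAMTS1 at 2 DPT.

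Fibroblast genes changed in both directions in N cells. DCN, the proteoglycan decorin, fell (-1.98, -2.74 and -3.18) and COL6A2 (-0.93, -1.21 and -1.91), while COL5A1 rose by 1.82, 1.86 and 1.44 and COL3A1 by 0.92, 1.25 and 0.95 in the authors' deposited tables. Of the matrix list 9, 7 and 5 of 24 tested members rose and 13, 13 and 14 fell. Medians were -0.28, -0.43 and -0.63 (adjusted permutation p = 0.0147, 0.0129 and 0.00247). ACTA2, smooth muscle actin, rose by 4.39, 3.30 and 2.20 and TGFB2 by 3.13, 3.29 and 3.10, while CNN1, a calponin of smooth muscle, fell (-1.51, -2.03 and -1.80) and CTGF, a matricellular target of YAP, (-2.07, -1.79 and -0.66). Of the myofibroblast and TGF-beta targets 11, 11 and 10 of the 19, 19 and 18 tested members rose and 5, 7 and 7 fell (12, 11 and 10 and 6, 7 and 7 adjusted over the list alone). Medians were 0.85, 0.50 and 0.61 (adjusted permutation p = 0.000991, 0.00447 and 0.00179).

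Genes of antioxidant defence and iron storage fell together. NQO1, a quinone reductase and target of NRF2, fell (-3.13, -4.00 and -3.51) in the authors' deposited tables, as did SLC7A11, the cystine transporter (-3.43, -3.70 and -2.54). The ferritin chains FTL (-2.03, -2.22 and -2.43) and FTH1 (-1.71, -2.07 and -2.01) fell, as did GPX4, which reduces lipid peroxides (-1.12, -1.44 and -1.45), in the deposited tables. In this list 0, 0 and 0 of 13 tested members rose and 13, 13 and 13 fell. Medians were -1.71, -1.58 and -2.01 (adjusted permutation p = 0.000991 at each time). Lipid synthesis fell as well: HMGCS1 (-1.86, -2.68 and -0.63), SCD, a desaturase, (-1.80, -3.16 and -1.59) and FADS2 (-2.07, -3.11 and -2.72). Of the sterol list 1, 1 and 3 of 18 tested members rose and 16, 17 and 14 fell. Medians were -1.17, -1.76 and -0.91 (adjusted permutation p = 0.000991 at each time). Of the fatty acid list 1, 1 and 1 of 10 tested members rose and 9, 9 and 7 fell. Medians were -1.51, -1.67 and -0.75 (adjusted permutation p = 0.000991, 0.000991 and 0.00994). Secreted inflammatory factors fell too, LIF (-2.50, -3.20 and -3.57) and ICAM1, an adhesion receptor, (-1.09, -2.39 and -3.12) in the deposited tables. In that list 1, 1 and 1 of the 9, 9 and 11 tested members rose and 4, 6 and 8 fell. Medians were -1.03, -1.31 and -1.27 (adjusted permutation p = 0.00247, 0.00179 and 0.00247).

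G2/M genes were lower in N cells than in GFP cells at 0.5 DPT and higher at 2 DPT. CDK1, the mitotic kinase, went from -1.01 to 2.97 in the authors' deposited tables, MKI67, a proliferation marker, from -0.93 to 2.91, TOP2A, a topoisomerase, from -1.64 to 2.78 and UBE2C, a mitotic ubiquitin enzyme, from -1.21 to 3.24. Of the 24 members 0, 8 and 24 of 24 tested members rose and 23, 5 and 0 fell. Medians were -1.28, 0.14 and 2.27 (adjusted permutation p = 0.000991, 0.317 and 0.000991). The GFP cells lost these transcripts over the same days, from a median of 20.9 FPKM at 0.5 DPT to 4.87 and 1.44, while the medians in N cells were 9.05, 4.93 and 6.67. FD cells had medians of 24.0, 2.66 and 1.04 FPKM and NFD cells 7.57, 1.23 and 1.24. In FD cells 10, 2 and 1 of 24 tested members rose and 0, 21 and 9 fell (9, 2 and 1 and 0, 21 and 9 adjusted over the list alone). Medians were 0.18, -0.89 and -0.31 (adjusted permutation p = 0.0942, 0.000991 and 0.0571) against GFP. Of the DNA replication list 2, 10 and 16 of the 23, 23 and 24 tested members rose and 16, 4 and 1 fell in N cells. Medians were -0.71, 0.27 and 0.69 (adjusted permutation p = 0.000991, 0.0804 and 0.000991). In FD cells 1, 0 and 1 of the 23, 22 and 23 tested members rose and 8, 12 and 10 fell (1, 0 and 0 and 8, 13 and 10 adjusted over the list alone). Medians were -0.24, -0.34 and -0.33 (adjusted permutation p = 0.00816, 0.0161 and 0.0161).

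**Figure D1:**
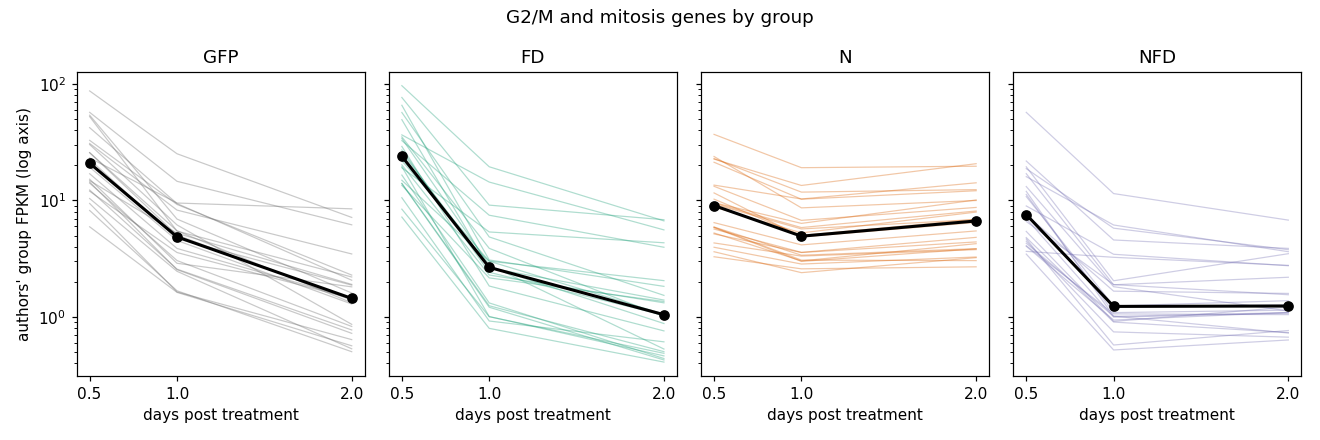
Authors' group FPKM (vertical log axis) of the 24 G2/M and mitosis genes at 0.5, 1 and 2 DPT (horizontal axis, days) in GFP, FD, N and NFD cells, with 1 thin line per gene and the list median in black. The median fell from 20.9 to 1.44 FPKM in GFP cells and went from 9.05 to 6.67 in N cells.

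In NFD cells, the proneural cascade was on as in N cells. HES6 rose by 4.72, 4.97 and 5.95, DLL3 by 6.20, 7.39 and 7.63 and GADD45G by 7.12, 7.55 and 7.06 in the authors' deposited tables. NEUROD4, a proneural factor, rose from 0 at 1 DPT and was 12.12 at 2 DPT without passing. CHGB rose by 6.77, 7.64 and 7.90, SCG2 by 7.43, 6.96 and 7.31 and SYP by 3.50 and 6.18 at 1 and 2 DPT. SCN2A, a neuronal sodium channel that GFP cells held at 3.45 FPKM at 2 DPT, fell (-1.82, -4.61 and -5.53), and TUBB3 fell (-0.42, -1.28 and -1.18). Of the proneural list 9, 13 and 11 of the 10, 16 and 16 tested members rose and 0, 0 and 0 fell (9, 14 and 11 and 0, 1 and 0 adjusted over the list alone). Medians were 5.20, 8.24 and 7.66 (adjusted permutation p = 0.000991 at each time). Over all members median levels in NFD cells were 0.277, 0.853 and 3.80 FPKM, against the GFP levels near 0 given above. Of the synapse list 8, 10 and 10 of the 13, 14 and 16 tested members rose and 3, 3 and 3 fell (9, 10 and 10 and 3, 3 and 3 adjusted over the list alone). Medians were 0.67, 1.05 and 1.80 (adjusted permutation p = 0.0666, 0.0129 and 0.000991). In the neuronal cytoskeleton list 2, 3 and 9 of the 9, 10 and 15 tested members rose and 4, 4 and 3 fell (2, 3 and 9 and 4, 5 and 3 adjusted over the list alone). Medians were -0.21, -0.24 and 1.03 (adjusted permutation p = 0.650, 0.535 and 0.159). NEFL, a neurofilament, rose at 0.5 and 2 DPT (4.02 and 7.50). Members of the muscle list rose here as well, CHRNA1 by 5.52, 6.94 and 6.78 and TNNT2 by 7.43, 6.66 and 5.05 in the deposited tables. In the muscle list 10, 6 and 9 of the 13, 12 and 14 tested members rose and 1, 2 and 0 fell. Medians were 4.48, 5.87 and 5.48 (adjusted permutation p = 0.000991 at each time). Muscle levels over all members had medians of 0.616, 0.992 and 1.39 FPKM in NFD cells, again against GFP levels near 0. The limits given for the proneural and muscle lists in N cells hold here too.

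Fibroblast genes fell in NFD cells, with list medians lower at each later time. DCN fell (-2.36, -3.75 and -5.21) and VIM (-1.12, -2.69 and -3.74) in the authors' deposited tables. THY1, a surface marker of fibroblasts, went from 0.47 to -0.54 and -2.66. Of the matrix list 8, 4 and 1 of 24 tested members rose and 13, 18 and 20 fell (8, 4 and 1 and 14, 18 and 20 adjusted over the list alone). Medians were -0.52, -1.41 and -2.48 (adjusted permutation p = 0.00557, 0.000991 and 0.000991). COL6A1 was the member that rose at 2 DPT (0.69). ACTA2 went from a rise of 3.33 and 0.79 to a value of -1.90, and CTGF (-4.60, -4.95 and -4.75) and CNN1 (-2.65, -4.03 and -4.07) fell in the deposited tables. Of the myofibroblast and TGF-beta targets 8, 6 and 2 of the 19, 19 and 18 tested members rose and 8, 11 and 14 fell. Medians were 0.06, -0.59 and -1.91 (adjusted permutation p = 0.992, 0.0165 and 0.000991). Of serum-response genes 8, 8 and 6 of the 21, 21 and 22 tested members rose and 10, 13 and 12 fell (8, 8 and 8 and 10, 13 and 12 adjusted over the list alone). Medians were -0.38, -0.81 and -0.45 (adjusted permutation p = 0.0770, 0.00317 and 0.0666). VCL, the adhesion protein vinculin, fell (-1.47, -2.11 and -2.53) in the deposited tables.

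Heat shock genes rose in NFD cells. HSPA1A (chromosome 6_qbl_hap6, 3076937 to 3079366), an inducible HSP70, rose by 3.97, 3.61 and 1.83 in the authors' deposited tables, HSPA1B by 3.57, 2.69 and 1.58, HSPH1, an HSP110, by 2.53, 2.83 and 1.62, and HSP90AA1, a cytosolic HSP90, at all 3 times, by 1.44 and 0.75 at 1 and 2 DPT. The mitochondrial chaperonins HSPE1 (1.81, 2.44 and 1.85) and HSPD1 (1.85, 2.09 and 1.47) rose too. HSPB1, a small heat shock protein, fell (-0.90, -0.77 and -1.31). In this list 9, 9 and 8 of 10 tested members rose and 1, 1 and 1 fell. Medians were 1.61, 1.86 and 1.11 (adjusted permutation p = 0.000991, 0.000991 and 0.00382). In FD cells 4, 1 and 0 of 10 tested members rose and 1, 4 and 4 fell (5, 1 and 0 and 2, 4 and 3 adjusted over the list alone). Medians were 0.28, -0.05 and -0.10 (adjusted permutation p = 0.0519, 0.772 and 0.759). In N cells 5, 5 and 4 of 10 tested members rose and 3, 3 and 2 fell. Medians were 0.16, 0.17 and 0.16 (adjusted permutation p = 0.460, 0.310 and 0.433).

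cAMP targets rose in NFD cells with medians that became smaller with time. NR4A1 rose by 6.17, 5.19 and 3.71, SIK1 by 4.42, 3.92 and 3.20 and RGS2 by 4.14, 2.57 and 0.82 in the authors' deposited tables. Of this list 20, 18 and 16 of the 27, 27 and 28 tested members rose and 5, 6 and 4 fell (20, 19 and 20 and 5, 7 and 4 adjusted over the list alone). Medians were 1.24, 0.82 and 0.51 (adjusted permutation p = 0.000991, 0.00382 and 0.148). In N cells, without the molecules, 8, 10 and 7 of the 23, 26 and 25 tested members rose and 11, 11 and 13 fell (8, 10 and 7 and 11, 11 and 14 adjusted over the list alone). Medians were -0.16, -0.18 and -0.35 (adjusted permutation p = 0.239, 0.273 and 0.0818). Of the BMP targets 10, 11 and 10 of the 19, 20 and 19 tested members rose and 6, 8 and 7 fell. Medians were 0.70, 0.61 and 0.61 (adjusted permutation p = 0.0145, 0.0505 and 0.0571). ID1 rose by 2.30, 3.02 and 3.66 while SMAD9, a BMP-responsive SMAD, fell (-0.99, -1.91 and -2.60). Antioxidant genes fell, NQO1 (-2.71, -3.76 and -3.27) and SLC7A11 (-3.52, -4.11 and -4.14) in the deposited tables. In that list 0, 0 and 0 of 13 tested members rose and 13, 10 and 12 fell (0, 0 and 0 and 13, 11 and 12 adjusted over the list alone). Medians were -1.55, -1.88 and -1.84 (adjusted permutation p = 0.000991 at each time). Of sterol genes 5, 2 and 4 of 18 tested members rose and 12, 14 and 11 fell. Medians were -0.63, -1.06 and -0.73 (adjusted permutation p = 0.00816, 0.000991 and 0.00613). Of fatty acid genes 1, 1 and 3 of 10 tested members rose and 9, 8 and 7 fell. Medians were -1.51, -1.64 and -0.95 (adjusted permutation p = 0.000991, 0.00179 and 0.0114). In the G2/M list 0, 1 and 5 of 24 tested members rose and 24, 21 and 8 fell. Medians were -1.33, -1.67 and 0.04 (adjusted permutation p = 0.000991, 0.000991 and 0.805). In the replication list 1, 4 and 7 of the 23, 23 and 24 tested members rose and 16, 12 and 7 fell (1, 5 and 7 and 16, 12 and 7 adjusted over the list alone). Medians were -1.01, -0.55 and -0.15 (adjusted permutation p = 0.000991, 0.0685 and 0.531).

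Across all genes, 4339 rose and 4239 fell in NFD cells at 0.5 DPT, 4540 and 4630 at 1 DPT, and 4855 and 4550 at 2 DPT, of 13538, 13930 and 14230 tested by the authors. At least 2-fold changes numbered 3347, 3988 and 4167, and 2771 rises and 2892 falls held at all 3 times. Among the 10 largest lasting rises were SYT7 (7.89, 9.68 and 10.41), IGFBPL1 (8.60, 10.11 and 10.23), SSTR2 (8.36, 9.13 and 9.17), TSPAN33, a tetraspanin (8.46, 9.62 and 8.44), and MYO7A, an unconventional myosin (6.03, 7.52 and 8.28) in the authors' deposited tables. These folds rest on GFP values under 0.5 FPKM. With a pseudocount of 1 the order at 2 DPT changed, to 7.53 for IGFBPL1, 6.79 for C11orf96, 6.71 for MGP, 6.31 for SSTR2 and 6.00 for SYT7. The 10 largest lasting falls held CASP1, the inflammasome protease (-4.00, -6.21 and -7.54), ADH1B, an alcohol dehydrogenase (-3.94, -5.64 and -7.23), ABI3BP, a matrix protein (-2.72, -5.11 and -7.00), EMP1, an epithelial membrane protein (-3.27, -5.20 and -5.89), and TEK, the angiopoietin receptor (-1.99, -4.28 and -5.87), in the deposited tables. With the pseudocount these were -5.34 for CASP1, -4.10 for ADH1B, -3.00 for ABI3BP, -4.43 for EMP1 and -3.92 for TEK at 2 DPT.

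**Figure D2:**
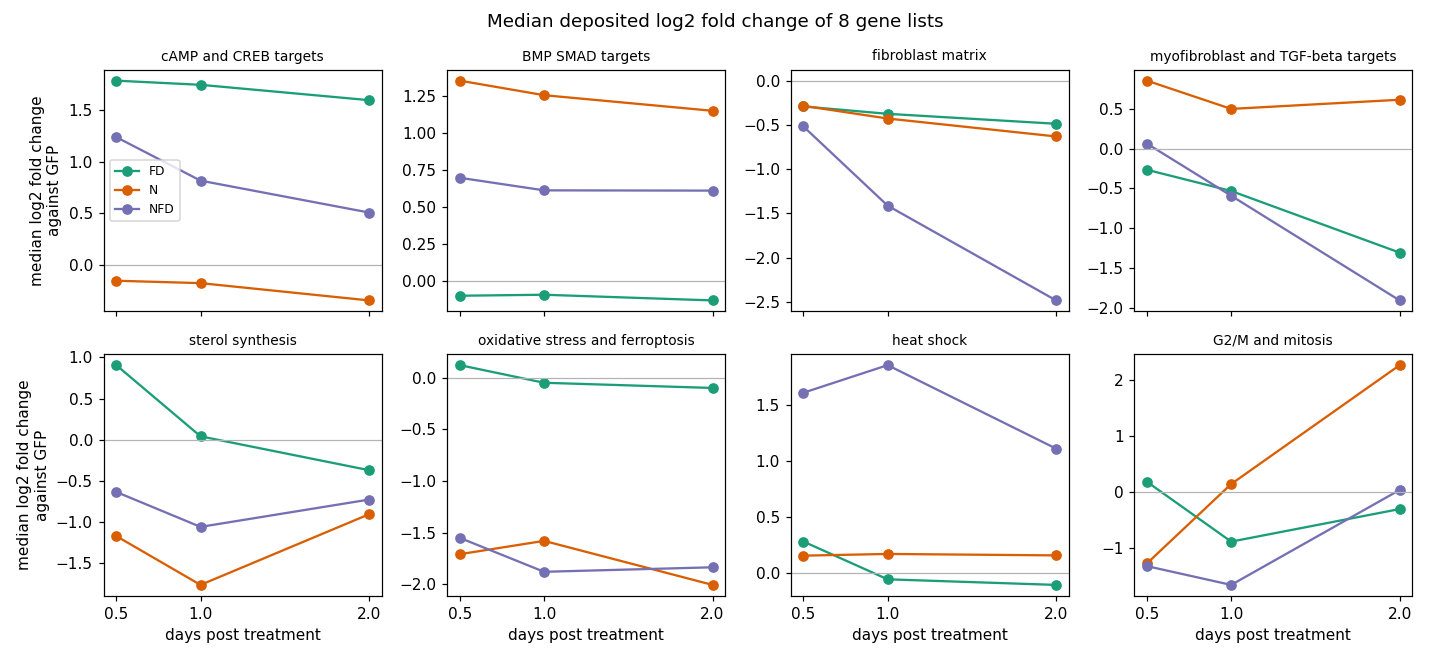
Medians of the authors' deposited log2 fold changes against GFP (vertical axes, each panel with its own scale) of 8 gene lists at 0.5, 1 and 2 DPT (horizontal axis, days), with 1 line each for FD, N and NFD cells. At 2 DPT the fibroblast matrix median was -0.49 in FD, -0.63 in N and -2.48 in NFD cells, and the heat shock median was -0.10, 0.16 and 1.11.

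NFD and N cells carried the same virus in the same medium. Their difference is what the molecules added to NEUROG2 only if both held a like level of it. No NEUROG2 value is given for NFD cells, so this was not tested. NFD was set against N here by the difference of the authors' deposited log2 fold changes against the same GFP groups. The 10 largest reductions at 2 DPT held ANGPT1, the angiopoietin ligand of TEK (chromosome 8, 108261709 to 108510254), which differed by -1.75, -3.76 and -5.11, with 49.2 FPKM in N and 1.43 in NFD cells at 2 DPT in the deposited tables. Among the others, VGLL3, a transcription cofactor, differed by -2.71, -3.69 and -4.54, EMP1 by -0.97, -2.56 and -4.26, CYR61 by -3.71, -3.83 and -4.32, TNC, the matrix protein tenascin C, by -0.11, -1.01 and -4.41, FBN2, a fibrillin, by -1.39, -2.89 and -4.30, and TSLP, an epithelial cytokine, by -2.84, -4.22 and -4.62. Among the 10 largest increases were NPTX1, a neuronal pentraxin that clusters glutamate receptors (0.45, 1.80 and 3.22), SSTR1, a somatostatin receptor (2.03, 2.34 and 3.36), HAP1, the huntingtin-associated protein (2.50 and 3.55 at 0.5 and 2 DPT), SPON1, the axon guidance protein F-spondin (1.33, 3.38 and 4.35), and CUZD1 (3.82, 5.50 and 5.41). With a pseudocount of 1 the differences at 2 DPT were -4.37 for ANGPT1, -3.30 for VGLL3, -2.89 for EMP1 and TSLP, -3.81 for CYR61 and -3.96 for FBN2. Among the increases they were 3.14 for NPTX1, 2.61 for SSTR1, 2.32 for HAP1, 3.59 for SPON1 and 4.18 for CUZD1.

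Differences of at least 2-fold between NFD and N numbered 1260 of 13220 genes at 0.5 DPT (466 higher and 794 lower in NFD), 1882 of 13403 at 1 DPT (717 and 1165) and 2156 of 13499 at 2 DPT (1053 and 1103). These counts carry no test. An approximate test chosen after the data were seen, with standard errors inferred from the authors' p-values and the spread of GFP counted in both tables, called 708 higher and 892 lower, 1234 and 1188, and 1269 and 1195. With the GFP spread left out it called 4421, 5168 and 5267. On simulated data that variant called 50% of genes changed by 1 on the log2 scale where the test above called 27%. The number that differ is therefore not settled by these tables.

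Gene groups were compared between NFD and N by medians and by members that passed, with no test of a whole list. Median differences of the matrix list were -0.16, -0.86 and -1.80, and the approximate test called 0, 1 and 1 higher and 1, 8 and 15 lower of 24. For myofibroblast and TGF-beta targets they were -0.56, -0.85 and -1.79, with 0, 0 and 0 higher and 5, 8 and 13 lower of 19, 19 and 18. COL1A1 differed by -0.39, -1.09 and -2.38, VIM by -0.71, -1.83 and -2.54, TAGLN by -0.53, -1.63 and -3.78 and ACTA2 by -1.07, -2.51 and -4.10, from the deposited fold changes. For cAMP targets the medians were 0.85, 1.00 and 0.90, with 10, 10 and 14 higher and 0, 2 and 2 lower of 23, 25 and 25, and DUSP1, a MAP kinase phosphatase induced by cAMP, differed by 3.27, 2.87 and 2.18. For heat shock genes they were 1.36, 1.58 and 0.79, with 6, 6 and 4 higher and 0, 0 and 0 lower of 10, HSPA1A differing by 3.28, 2.76 and 1.71. For BMP targets the medians were -0.73, -0.84 and -0.74, with 0, 0 and 0 higher and 4, 7 and 7 lower of 19, 20 and 19, ID2 differing by -2.48, -2.41 and -2.36 and SMAD9 by -2.10, -2.90 and -3.40. G2/M genes differed by -0.07, -1.84 and -2.15, with 0, 0 and 0 higher and 1, 20 and 20 lower of 24, and replication genes by -0.23, -0.68 and -0.68, with 0, 0 and 0 higher and 1, 9 and 9 lower of 23, 22 and 24. Sterol genes differed by 0.80, 0.74 and 0.51, with 5, 3 and 5 higher and 0, 0 and 1 lower of 18.

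For neuronal genes the approximate test, which called 43% of simulated differences of 2 on the log2 scale, leaves much undecided. That share is over all genes, and the inferred standard errors grow with the fold against GFP. For genes far above GFP in both conditions, such as HES6 and GADD45G, differences of the size seen could not pass. The lack of calls there says nothing on whether NFD and N differ. Proneural genes had median differences of -0.31, 0.08 and 1.53, with 7 of 13 at least 2-fold higher and 1 lower in NFD at 2 DPT, and the approximate test called 0, 0 and 0 higher and 1, 1 and 1 lower of 9, 9 and 13. HES6 differed by -0.31, 0.41 and 2.14 and GADD45G by 1.37, 1.31 and 1.53, without passing. Synapse genes had 0.30, 0.62 and 0.00, with 1, 3 and 1 higher and 1, 2 and 1 lower of 13, 12 and 13, and SCN2A differed by -1.80, -3.36 and -3.46, passing at 0.5 and 1 DPT. Neuronal cytoskeleton genes had 0.06, -0.12 and 0.11, with 1, 0 and 2 higher and 2, 1 and 1 lower of 9, 10 and 13. VGF, a neurosecretory peptide precursor, differed by 0.85, 1.05 and 3.26, passing at 2 DPT, from the authors' deposited fold changes.

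Whether the combination departed from the sum of its parts was measured as the NFD log2 fold change minus those of N and FD, all from the authors' deposited tables. NPTX1 lay above the sum by 0.68, 2.78 and 4.32, while INHBA, an activin subunit, was -2.20, -2.45 and -3.26, SMAD9 -2.21, -3.31 and -2.83 and ANGPT1 -1.93, -4.00 and -4.42. No test of a whole list was run against the sum. Heat shock genes had medians of 1.39, 1.65 and 1.00, and the approximate test called 3, 6 and 5 above and 0, 0 and 0 below of 10. G2/M genes had -0.23, -1.05 and -1.84, with 0, 0 and 0 above and 1, 5 and 13 below of 24. Matrix genes had 0.06, -0.33 and -1.10, with 1, 0 and 1 above and 0, 3 and 4 below of 24, and cAMP targets -0.29, -0.78 and -0.56, with 0, 1 and 3 above and 2, 3 and 4 below of 23, 25 and 25. Departures of at least 2-fold numbered 923 of 12803 genes (459 above and 464 below), 1855 of 12902 (920 and 935) and 2157 of 13031 (1104 and 1053), with no test. The approximate test called 217 above and 192 below, 970 and 765, and 1128 and 908. With 1 copy of the GFP spread kept it called 1097, 3147 and 3422 in all.

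The effect of each condition changed with time. By the approximate test, the fold change against GFP differed between 0.5 and 2 DPT for 1332 of 12139 genes in FD, 1626 of 12849 in N and 2924 of 12923 in NFD cells. All 24 G2/M genes differed upward in N cells, with a median difference of 3.46, 15 did in NFD cells (median 1.25), and in FD cells 1 differed upward and 8 downward (median -0.60). GFP cells themselves changed over these days, so a change of the fold with time is not a change of the treated cells alone.

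The conditions shared part of their genes. At 2 DPT, 2714 genes rose and 3099 fell in both N and NFD cells, where independent lists would share 1196 and 1382 and simulated unchanged groups with a shared control 25.9 and 26.3. The covariance of their fold changes was 1.77 against 0.224 in the simulation, and the correlation 0.857 against 0.461. Opposite calls numbered 281 and 231. For FD and NFD cells, 1128 rose and 1821 fell in both, against 687 and 992 if independent and 25.0 and 25.5 simulated, with a covariance of 0.389 against 0.0748 and a correlation of 0.442 against 0.401. Opposite calls numbered 537 and 497. For FD and N cells, 878 and 1534 were shared, against 545 and 904 if independent and 25.0 and 25.4 simulated, with a covariance of 0.201 against 0.0688. Their correlation of 0.299 was below the 0.421 of the simulation (0.202 against 0.438 at 0.5 DPT). The simulated correlation is that of spread alone around a shared control, set by the assumed 0.5. Unrelated true effects would also lower it, so a smaller value does not show that the effects oppose each other. Apart from this, 596 genes higher and 574 lower in FD were called the other way in N. At 0.5 DPT the shared counts were 2630 and 2714 for N and NFD (1084 and 1050 if independent), 1419 and 1617 for FD and NFD (692 and 803), and 813 and 1104 for FD and N (549 and 624). All 3 comparisons of a time use the same GFP libraries, which could not be split here, so part of the excess may come from the shared control. The simulated counts are for groups with no changed genes. They cannot show how much a shared control adds to the overlap among genes that do change.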

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

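Among the tests in this part, the change of the control group, the bound on reads carried over, the glial genes and the share of NEUROG2 were chosen after the results they bear on were seen.

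Effects against GFP that differed between 0.5 and 2 DPT by the approximate test, with calls in opposite directions at these times, drew attention to themselves as a difference between groups. They numbered 234 genes in FD cells (127 lower then higher, 107 higher then lower), 468 in N cells (266 and 202) and 610 in NFD cells (287 and 323). The G2/M list differed most plainly in N cells. There the differences of its members' log2 fold changes, 2 minus 0.5 DPT, had a median of 3.46, with all 24 past the approximate test. Genes with opposite calls nearly always pass that test, so it adds little to the calls themselves. Without it, opposite calls numbered 234 in FD, 469 in N and 611 in NFD cells.

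The G2/M reversal in N cells was set against a change of the GFP control and against scaling. The authors' group FPKM of all 24 genes fell in GFP cells from 0.5 to 2 DPT, with a median log2 change of -3.90, and N cells changed by -0.30 over the same days, with 22 of 24 lower. The rise of the fold change is therefore consistent with a loss of these transcripts in the control while N cells kept them. A scaling difference between times is argued against by 10874 expressed genes, whose median change differed by -0.0745 between N and GFP. FD (-4.43) and NFD (-2.53) cells lost them too, and since GFP cells received no molecules, these are not needed for the loss. Whether cell density or a change of medium caused it stays open and was not tested.

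FD cells at 2 DPT held low levels of 12 neuronal transcripts at least 4 times those in GFP and earlier FD cells, and GRIA2 at 1.18 FPKM, the cortical factor TBR1 and the RNA-binding protein ELAVL4 were at least 4 times every other group. Of the 68 neuronal list members, 4 were among the 42 such transcripts of 21941 (exact Fisher test p = 8.64e-06), and 14 of the 42 were small RNAs. Neuronal members among these transcripts were the pattern that drew attention. The test restates it and cannot decide whether they are chance highs near the detection limit. Whole brain RNA is argued against by glial genes, of which 1 of 6 was as specific, AQP4 at 0.00444 FPKM, while GFAP was 0.0379 in FD and 0.0730 in GFP. Reads carried over from the NEUROG2 libraries would have to make up at least 5.07% of the highest N or NFD level to give any of the 12 (SLC17A7, the least demanding), while 14 of 2759 transcripts of at least 20 FPKM in every N and NFD group stood below that share in FD, IGFBPL1 at 0.797% and TAC3 at 0.930% among them, which argues against carry-over. A small admixture of neuronal RNA from outside these libraries may remain, and no biological explanation was tested.

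NEUROG2 was listed at 36.7 FPKM in GFP cells at 0.5 DPT, 1.4% of its level in N cells, and at 0.720% and 0.580% later. If reads or cells of the N group had been carried over, every transcript abundant in N would hold at least that share in GFP. Of 3570 transcripts of at least 20 FPKM in N, 9 held less at 0.5 DPT, among them IGFBPL1 with 0.188%, MGP with 0.219% and TNNT2 with 0.309%, where small RNAs were left out after values were seen, which argues against carry-over as the whole source. Nor did its targets follow it, since the 8 proneural genes above 0.1 FPKM were lower in GFP cells at 0.5 than at 2 DPT, with a median of -0.57. Transcription of the fibroblasts' own gene and reads from vector sequence stay open and were not tested.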

How the results depend on the processing

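The variants of the approximate test and the omission of group-specific genes were chosen after the data were seen, and the other alternatives before. All 9 counts of changed genes kept within 1.5 times their value at a q-value of 0.01 and with at least 1 FPKM in either group. Centring kept the authors' calls, so it could not change these counts, only their split into rises and falls. It left the counts of rises unchanged (medians of expressed genes lay between -0.0379 and 0.0294), which says little with medians so near 0. The counts of changed genes fell with at least a 2-fold change, by its own construction: in FD to 794, 990 and 1103 (from 4748, 5017 and 5119), in N to 2131, 2506 and 2788 (from 6827, 7501 and 7868), and in NFD to 3347, 3988 and 4167 (from 8578, 9170 and 9405). Shared rises of FD and N went from 813 to 540 at 0.5 DPT and from 878 to 584 at 2 DPT at a q-value of 0.01. The number of genes differing between NFD and N depended on the measure. The counts at 2-fold with no test were 1260, 1882 and 2156. The approximate test gave 741 at 0.5 and 1360 at 2 DPT for a q-value of 0.01. It gave 587, 980 and 1084 with a 2-fold difference added, and 4421, 5168 and 5267 with the GFP spread left out. Against the sum of both effects, counts of 923, 1855 and 2157 became 409 at a q-value of 0.05 at 0.5 DPT. They became 207, 919 and 1147 at 0.01, and 267, 916 and 1132 with a 2-fold difference added. With 1 copy of the GFP spread kept they became 3147 and 3422 at 1 and 2 DPT. The cause was not tested for those that are not stricter by construction. Of 317 list medians, 146 passed, 143 with a pseudocount of 1 (11 lost, 9 gained), 144 with 0.1 (3 and 1), 143 of 298 with at least 1 FPKM (5 and 9) and 148 centred (0 and 2). The median of the list axon guidance and migration, N against GFP, 0.5 DPT, turned from 0.60 to -0.00342 with at least 1 FPKM, and the cause was not tested. A pseudocount of 1 moved 285 fold changes of named genes, and by its construction it cannot turn their direction. No paired analysis was possible because the tables hold 1 value per group, and for the same reason leaving out a replicate, a replicate block and other splits of the samples were not run. Bonferroni says nothing here, since the smallest deposited p-value gives an adjusted p of 0.648 to 0.712. Depth is unknown, so what it limits was not assessed.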

Other observations

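Values in this part are given without a test of their cause, and the genes named here were chosen from the fixed lists after their values were seen.

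At 2 DPT SLC18A3, the vesicular acetylcholine transporter, was listed at 0 in GFP cells and rose to 6.12 FPKM in N and 6.71 in NFD cells in the authors' deposited tables. At 0.5 and 1 DPT it did not pass. GAD1, an enzyme of GABA synthesis, rose by 2.93 and 3.35 in NFD cells at 1 and 2 DPT. Of motor neuron and cholinergic genes 1, 1 and 1 rose and 0, 0 and 0 fell of 1 in FD and 2, 1 and 3 rose and 0, 0 and 0 fell of 3, 4 and 3 in N (3, 1 and 3 and 0, 0 and 0 adjusted over the list alone). In the same list 2, 2 and 2 rose and 0, 0 and 0 fell of 3, 4 and 3 in NFD (3, 2 and 3 and 0, 0 and 0 adjusted over the list alone). Motor neuron medians in NFD were 1.80, 5.30 and 1.34 (adjusted permutation p = 0.230, 0.0459 and 0.372). In N they were 1.23 (adjusted permutation p = 0.325) at 0.5 DPT and 5.23 (adjusted permutation p = 0.0342) at 1 DPT, and the list passed at 2 DPT (adjusted permutation p = 0.00179) with a median member listed at 0 in GFP. Of other subtypes 0, 0 and 0 rose and 0, 0 and 0 fell of 0, 0 and 1 in FD (0, 0 and 1 and 0, 0 and 0 adjusted over the list alone) and 1, 1 and 1 rose and 0, 0 and 0 fell of 2, 3 and 3 in N (1, 3 and 3 and 0, 0 and 0 adjusted over the list alone). Here 1, 3 and 4 rose and 0, 0 and 0 fell of 3, 5 and 6 in NFD (1, 5 and 6 and 0, 0 and 0 adjusted over the list alone). Medians in NFD were 7.18, 6.19 and 9.82 (adjusted permutation p = 0.0169, 0.0105 and 0.00719), and in N 5.87 (adjusted permutation p = 0.0218) at 1 DPT and 6.85 (adjusted permutation p = 0.00613) at 2 DPT. In GFP cells the median level was 0, 0.00378 and 0 FPKM for motor neuron genes. For other subtypes it was 0.00234, 0.00131 and 0.00114 FPKM, so the folds of both lists rest on values near 0. The lists hold 12 motor neuron and 20 other subtype genes, and members near 0 in GFP cells were mostly tested only where the other group was higher. Positive medians of these lists are partly fixed by that selection, so their p-values add little. Of the proneural list 1, 2 and 2 rose and 1, 1 and 1 fell of 5 in FD and of the neuronal cytoskeleton list 1, 3 and 2 rose and 2, 4 and 3 fell of 8, 10 and 10 in FD, where no median passed. Of neural progenitor genes 0, 0 and 0 rose and 1, 1 and 1 fell of 1 in FD and 2, 1 and 2 rose and 0, 0 and 0 fell of 3, 2 and 2 in N. Among these 1, 1 and 2 rose and 0, 0 and 0 fell of 1, 2 and 2 in NFD, NES falling in FD (-0.42, -0.93 and -1.09). Of neural crest genes 2, 2 and 1 rose and 0, 0 and 0 fell of 4, 3 and 2 in FD and 0, 0 and 1 rose and 2, 2 and 2 fell of 3 in N. For this list 0, 1 and 2 rose and 2, 2 and 2 fell of 3, 4 and 4 in NFD, with no median past the test. Of glial genes 2, 3 and 3 rose and 3, 3 and 4 fell of 6, 6 and 7 in N and 3, 5 and 6 rose and 3, 2 and 3 fell of 7, 7 and 9 in NFD. Medians in NFD were 1.86, 0.92 and 0.54 (adjusted permutation p = 0.00776, 0.109 and 0.659), and none passed in N. Of endothelial and blood genes 2, 2 and 2 rose and 0, 0 and 0 fell of 3 in FD and 1, 1 and 0 rose and 2, 2 and 2 fell of 4, 4 and 3 in N. In the same list 1, 3 and 4 rose and 2, 2 and 2 fell of 5, 6 and 7 in NFD, where VWF, a clotting protein of endothelium, rose by 2.21, 4.42 and 4.38. Endothelial medians were 0.83, 0.86 and 0.88 (adjusted permutation p = 0.0321, 0.0272 and 0.0399) in FD, -0.28, -0.34 and -1.96 (adjusted permutation p = 0.447, 0.447 and 0.0186) in N and 2.21, 5.18 and 4.38 (adjusted permutation p = 0.0298, 0.00179 and 0.0109) in NFD. Of muscle genes 0, 0 and 1 rose and 2, 3 and 3 fell of 5, 5 and 7 in FD, with no median past the test.

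Signalling groups outside the report moved as follows. Of Notch genes 5, 4 and 4 rose and 2, 3 and 2 fell of 10 in N and 5, 5 and 5 rose and 5, 4 and 4 fell of 10, 11 and 10 in NFD (5, 5 and 6 and 5, 4 and 4 adjusted over the list alone), and LFNG, a modifier of Notch, rose by 3.22, 1.94 and 2.16 in NFD in the authors' deposited tables. Of SOXC factors 1, 1 and 0 rose and 1, 1 and 1 fell of 3 in N (1, 1 and 0 and 2, 1 and 1 adjusted over the list alone) and 2, 1 and 2 rose and 1, 1 and 1 fell of 3 in NFD. Of adenylyl cyclase and PKA genes 4, 4 and 4 rose and 8, 12 and 8 fell of 17 in N (4, 4 and 6 and 8, 12 and 8 adjusted over the list alone) and 5, 6 and 5 rose and 5, 6 and 8 fell of 16, 17 and 17 in NFD. Of serum-response genes 6, 8 and 8 rose and 6, 7 and 10 fell of 19, 22 and 22 in N (6, 9 and 8 and 6, 7 and 11 adjusted over the list alone). No median of these 4 groups passed in N, and the Notch medians in NFD were 0.15, 1.14 and 1.22 (adjusted permutation p = 0.690, 0.0173 and 0.00719). Of axon guidance genes 4, 4 and 6 rose and 6, 5 and 7 fell of 14 in FD (4, 4 and 6 and 7, 5 and 7 adjusted over the list alone) and 8, 11 and 10 rose and 5, 4 and 5 fell of 15, 17 and 17 in N (8, 12 and 10 and 5, 4 and 5 adjusted over the list alone). Here 6, 8 and 8 rose and 4, 8 and 7 fell of 15, 16 and 17 in NFD. Medians in N were 0.60, 0.43 and 0.99 (adjusted permutation p = 0.0180, 0.0770 and 0.00179), although the 0.5 DPT median was near 0 and reversed in sign among members of at least 1 FPKM. ROBO2, a SLIT receptor, rose by 2.61, 3.21 and 3.57. Of neuropeptides and growth factors 3, 3 and 4 rose and 3, 2 and 2 fell of 8, 8 and 9 in FD and 4, 4 and 3 rose and 5, 4 and 5 fell of 9, 9 and 11 in N (4, 4 and 3 and 5, 5 and 5 adjusted over the list alone). Among these 3, 4 and 4 rose and 5, 5 and 4 fell of 10, 9 and 12 in NFD, where GAL, the peptide galanin, rose by 3.20, 4.37 and 5.05 and HGF, a growth factor of fibroblasts, fell in NFD (-1.60, -3.13 and -3.94). Medians in NFD were -0.65, -1.14 and 0.99 (adjusted permutation p = 0.111, 0.0274 and 0.165), and none passed in FD or N. Of EMT regulators 4, 3 and 3 rose and 5, 6 and 7 fell of 11, 12 and 12 in FD (4, 3 and 3 and 5, 7 and 7 adjusted over the list alone) and 4, 3 and 3 rose and 7, 7 and 7 fell of 12, 12 and 11 in N. For this list 4, 3 and 3 rose and 6, 7 and 8 fell of 12 in NFD, with SNAI1, a repressor of epithelial genes, up by 3.69, 3.67 and 3.61 in N. The EMT medians were -0.17, -0.36 and -0.52 (adjusted permutation p = 0.235, 0.0593 and 0.00504) in FD, -0.48, -0.58 and -0.82 (adjusted permutation p = 0.0260, 0.0186 and 0.00719) in N and -0.13, -0.59 and -0.80 (adjusted permutation p = 0.650, 0.117 and 0.0195) in NFD. Of inflammatory genes 4, 2 and 3 rose and 5, 6 and 6 fell of 10, 9 and 12 in NFD. Medians were -0.75, -1.31 and -0.66 (adjusted permutation p = 0.0505, 0.00816 and 0.0597). Of interferon genes 4, 3 and 5 rose and 4, 7 and 9 fell of 17, 18 and 18 in FD and 4, 5 and 5 rose and 9, 7 and 10 fell of 16, 19 and 19 in N. In the same list 5, 5 and 11 rose and 10, 10 and 8 fell of 17, 19 and 21 in NFD (5, 6 and 11 and 10, 10 and 8 adjusted over the list alone). Medians in NFD were -0.94, -0.66 and 0.62 (adjusted permutation p = 0.00557, 0.0499 and 0.109), and in N -0.44, -0.25 and -0.39 (adjusted permutation p = 0.0191, 0.228 and 0.109).

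Of p53 targets 0, 3 and 3 rose and 11, 6 and 4 fell of 16 in FD (0, 3 and 2 and 11, 6 and 4 adjusted over the list alone) and 6, 2 and 1 rose and 5, 4 and 6 fell of 16, 15 and 16 in N. Here 6, 4 and 6 rose and 4, 8 and 5 fell of 16 in NFD. Medians in FD were -0.46, -0.16 and -0.19 (adjusted permutation p = 0.000991, 0.122 and 0.240), and none passed in N or NFD. BBC3, an inducer of apoptosis, fell in FD (-1.16, -0.87 and -0.46) in the authors' deposited tables. Of CDK inhibitors 0, 1 and 2 rose and 4, 3 and 2 fell of 8 in FD and 0, 1 and 2 rose and 8, 5 and 5 fell of 8, 7 and 8 in N. Among these 1, 3 and 3 rose and 5, 5 and 4 fell of 8 in NFD, and CDKN1C rose in FD from 1 DPT (1.34 and 1.93). The medians were -0.60, -0.54 and -0.66 (adjusted permutation p = 0.0191, 0.0886 and 0.0524) in N, and in NFD that at 0.5 DPT was -0.76 (adjusted permutation p = 0.0298), the one at 1 DPT passed and the one at 2 DPT did not. Of ATF4 and ER stress genes 5, 3 and 3 rose and 8, 10 and 6 fell of 16 in FD and 2, 1 and 1 rose and 12, 14 and 11 fell of 16 in N. For this list 4, 4 and 3 rose and 8, 12 and 11 fell of 16 in NFD. Medians in N were -0.51, -0.90 and -0.50 (adjusted permutation p = 0.00447, 0.000991 and 0.0268), in FD -0.19, -0.42 and 0.08 (adjusted permutation p = 0.0308, 0.00247 and 0.397) and in NFD -0.18, -0.88 and -0.64 (adjusted permutation p = 0.373, 0.00247 and 0.0189). Of oxidative stress genes 5, 1 and 3 rose and 0, 4 and 5 fell of 13 in FD (5, 1 and 4 and 0, 4 and 5 adjusted over the list alone), with no median past the test. Of hypoxia genes 6, 5 and 2 rose and 3, 4 and 6 fell of 14 in FD and 5, 2 and 6 rose and 4, 7 and 4 fell of 14 in N. In the same list 6, 8 and 6 rose and 3, 2 and 3 fell of 14 in NFD (6, 8 and 6 and 3, 3 and 3 adjusted over the list alone). Medians in FD were 0.25, 0.10 and -0.05 (adjusted permutation p = 0.0393, 0.350 and 0.994), and none passed in N or NFD. Of chromatin remodelling genes 5, 4 and 3 rose and 2, 2 and 3 fell of 27 in FD (5, 1 and 1 and 2, 2 and 1 adjusted over the list alone) and 9, 11 and 10 rose and 7, 7 and 5 fell of 28 in N (9, 12 and 10 and 7, 7 and 5 adjusted over the list alone). Here 10, 11 and 11 rose and 9, 9 and 9 fell of 28 in NFD (10, 11 and 11 and 9, 10 and 9 adjusted over the list alone), with no median past the test, while CHD7, a chromatin remodeller of neural development, rose by 5.62, 6.67 and 7.26 in NFD. Of histones 0, 1 and 3 rose and 12, 5 and 4 fell of 14 in FD (0, 1 and 2 and 12, 5 and 4 adjusted over the list alone) and 1, 8 and 10 rose and 11, 2 and 0 fell of 14 in N (1, 8 and 10 and 11, 3 and 0 adjusted over the list alone). Among these 1, 6 and 8 rose and 12, 6 and 4 fell of 14 in NFD (1, 6 and 8 and 13, 6 and 4 adjusted over the list alone). Medians in NFD were -1.45, -0.01 and 0.41 (adjusted permutation p = 0.000991, 0.826 and 0.129), in FD -0.75, -0.10 and -0.02 (adjusted permutation p = 0.000991, 0.447 and 0.669) and in N -0.61, 0.45 and 0.77 (adjusted permutation p = 0.00557, 0.0109 and 0.00382). Of ribosomal proteins 0, 0 and 0 rose and 1, 2 and 15 fell of 15 in FD (0, 0 and 0 and 0, 2 and 15 adjusted over the list alone) and 8, 1 and 0 rose and 0, 1 and 3 fell of 15 in N (8, 1 and 0 and 0, 1 and 2 adjusted over the list alone). For this list 3, 0 and 0 rose and 0, 3 and 15 fell of 15 in NFD (2, 0 and 0 and 0, 3 and 15 adjusted over the list alone). The median in NFD at 2 DPT, -0.70 (adjusted permutation p = 0.0308), passed and that in FD, -0.47 (adjusted permutation p = 0.0634), did not. Of housekeeping genes 3, 2 and 2 rose and 1, 1 and 3 fell of 12 in FD and 1, 0 and 1 rose and 3, 7 and 4 fell of 12 in N (0, 0 and 0 and 3, 7 and 4 adjusted over the list alone). In the same list 4, 3 and 1 rose and 3, 5 and 5 fell of 12 in NFD, with no median past the test.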
